A study of Mus musculus with 10 samples.

How the data were processed

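Poly(A)-selected RNA from whole liver was sequenced as paired reads on an Illumina NovaSeq, per the labels' protocols. The deposited table held 24537 genes and 1 column for each of the 10 libraries. The submitters' processing notes name STAR and HOMER and the GRCm38 (mm10) build, with versions not given in the sources used here. Per the file headers, the authors made the expected counts with HOMER by counting tags over exons on 1 strand, with transcripts condensed to 1 entry per gene and no normalization. All values were multiples of 0.5, and 51.7% of the nonzero values were not whole numbers, so they were handled like expected counts and rounded to whole numbers (0.5 upwards) before testing. The design written beforehand had assumed whole counts, and the test was kept. The reason for the steps of 0.5 is not given in the sources used here. Whether the library kit marks strand is also not given, so reads of a gene and of an antisense partner cannot be told apart. The columns summed to between 43.0% and 43.7% of the library totals in the header. The table holds no mitochondrially encoded genes, and these were not analysed here. Each row named a gene, and each column matched 1 sample by its library name.

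Samples were grouped by the treatment label, with replicates numbered in accession order, a number that pairs nothing. Pairs of libraries were compared by a chi-square test over genes with at least 20 counts in the pair. The smallest chi-square per gene was 8.00, so no library was a repeat of another.

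Genes were tested with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M values (TMM) normalization, the filterByExpr filter (minimum count 10, minimum total 15) and the quasi-likelihood F test without robust fitting. The filter left 12186 genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were set so that the squared ratio of estimate to error equals the F statistic. CPM values use the TMM-scaled library sizes. The precision at this depth is limited by counts: 3 counts in a library correspond to between 0.220 and 0.383 CPM, and such limits cover counting error only.

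Before the data were examined, 46 gene lists were written, for interferon responses, other liver pathways, cell types that a liver can hold and signs of RNA quality. The 40 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) and, as alternatives, with an estimated correlation and with fry. Of the 1044 symbols written, 1011 were in the table, 3 of them by an alias. A score per liver was the mean log2 CPM (prior count 2) over the tested members of a list, compared by a two-sided exact permutation test and adjusted over the lists. The genes named in the text follow a rule fixed beforehand, apart from those said to be chosen after their values were seen. It takes the 12 largest changes per direction among genes past the threshold with a mean of at least 1 CPM and all 5 anti-IFN livers on 1 side of the IgG mean. Where none passed in a direction, it takes the 5 with the smallest p. It adds the 3 members with the smallest p of each list described, and 9 genes chosen for the treatment, among them Ifnar1, Ifnar2, Ifngr1, Ifngr2, Irf7, Isg15, Cd274 and Cxcl9. Some genes that meet the rule are left out of the text.

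The steps were tested on simulated data for this comparison, with 12093 genes drawn from the real means and library sizes. At a log2 fold change of 2, 100% of 65 changed genes were recovered, at 1 it was 87.5% of 64, and at 0.5 it was 36.4% of 66. Among the 166 simulated calls 5.42% were false, and of 100 random lists 0 were called by camera. The simulated genes were drawn independently of each other, whereas members of the real lists were correlated (estimated at 0.726 for type I interferon-stimulated genes). The simulation therefore does not show how often camera with the preset correlation calls a correlated list falsely.

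Alternatives were other scalings (DESeq2 size factors, upper quartile, library size alone), other filters, robust fitting, the DESeq2 1.42.0 Wald test, limma-voom with library weights, an adjusted p under 0.1, and leaving out each liver in turn. Alternatives chosen after seeing the data were doubled values in place of rounding, the header's library totals, and an index of clock genes per liver as a covariate. Figures were drawn with matplotlib 3.10.9.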

Results

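The data were RNA sequencing counts from whole livers of 10 old male C57BL/6J mice, an inbred laboratory strain. Of these mice, 5 received antibodies that block interferon (the anti-IFN group) and 5 received control immunoglobulin G (the IgG group). Each antibody was given into the abdominal cavity at 10 mg/kg on Mondays, Wednesdays and Fridays for 21 days. Interferons are secreted signalling proteins that switch on antiviral and antigen presentation genes. The labels do not name the interferon or receptor that was blocked. All mice shared a birth date and a cull date. The labels give each library a name of its own but no animal number, so the p-values of single genes and of scores per liver measure the spread between these 10 samples. Rounded gene counts summed to between 7827500 and 13623789 per library, and a count of 1 corresponded to between 0.0734 and 0.128 CPM (counts scaled to a common library size). The series title places the work in a study of interferon signalling and liver cancer in old age. The single comparison asked which liver transcripts differed after interferon blockade.

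Interferon-stimulated and antigen presentation transcripts fell in the anti-IFN livers, and no gene rose past the test. Irf7, a transcription factor that amplifies interferon responses, fell from 70.4 ± 42.0 CPM (SD, n = 5) with IgG to 6.98 ± 1.31 CPM with anti-IFN (n = 5), a 10.1-fold fall. Usp18, a protease that removes the ubiquitin-like protein Isg15 from other proteins, fell from 12.0 ± 11.4 to 0.575 ± 0.138 CPM, a log2 fold change of -4.33, or -3.55 without IgG replicate 3, which was at 32.2 CPM. Irf9, the DNA-binding part of the complex that carries type I interferon signals, had the smallest p of all genes and fell from 41.1 ± 10.3 to 10.2 ± 1.40 CPM. Transcripts of the antigen presentation genes H2-D1 and Tap1 also fell, by less: H2-D1 went from 707 ± 31.6 to 482 ± 56.0 CPM, and Tap1 from 37.0 ± 9.21 to 18.3 ± 1.67 CPM.

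With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 52 of 12186 tested genes had an adjusted p under 0.05. All 52 were lower in the anti-IFN group and 0 were higher. At an unadjusted p under 0.05, 418 genes were higher and 402 lower in edgeR, a balance that depends on the use of scaling factors (here the trimmed mean of M values). With library size alone 190 were higher and 720 lower, and with the authors' library totals (chosen after seeing the data) 182 and 741, and in both fits 0 genes were called higher after adjustment. The DESeq2 Wald test called 16 genes higher and 97 lower, and limma-voom with library weights called 2 higher and 47 lower. The median log2 fold change among the 52 was -1.90, with a range from -5.09 to -0.36. Of the called genes, 37 fell more than 2-fold and 26 more than 4-fold. For each of the 52, all 5 anti-IFN livers lay below all 5 IgG livers. Across all tested genes 1.55% had groups that did not overlap, where chance gives 0.794%. The genes H2-L and H2-D1 overlap on chromosome 17, as do H2-Q6 and H2-Q8, so these calls can share reads, and the 52 genes stand for 50 separate loci.

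Among called genes with a mean of at least 1 CPM, the 12 with the largest falls were Ifi44, Usp18, Ifit1, Apol9a, Ifit3, Gbp10, Irf7, Oas2, Tgtp1, Gm12250, Ifit3b and Apol9b. Their log2 fold changes ran from -5.09 (SE 0.96) for Ifi44 to -2.99 (SE 0.29) for Apol9b. IgG replicate 3 was high in several of them. Without it the log2 fold change was -3.96 for Ifi44 (-6.07 to -3.96 over all alternatives), -3.55 for Usp18, -3.59 for Ifit1, -2.66 for Gbp10 (against -3.35 with all livers) and -2.42 for Tgtp1 (against -3.20), and all 5 were still called. On the GRCm38 (mm10) build, Irf7 lies on chromosome 7 from 141263183 to 141266424, and Usp18 on chromosome 6 from 121245906 to 121270917. The log2 fold change was -3.33 (SE 0.33) for Irf7, with an edgeR adjusted p of 0.000379. For Usp18 it was -4.33 (SE 0.62), with an edgeR adjusted p of 0.00639. Irf9, on chromosome 14 from 55603985 to 55610030, had a log2 fold change of -2.02 (SE 0.16) and an edgeR adjusted p of 0.000202. Ifit1, whose protein binds viral RNA, fell from 11.1 ± 9.05 to 0.584 ± 0.211 CPM. It lies on chromosome 19 from 34640889 to 34650009, near Ifit3, which fell 11.2-fold. Oas2, a sensor of double-stranded RNA, fell from 4.04 ± 1.46 to 0.418 ± 0.196 CPM. Ifi44 lay near the counting limit in the anti-IFN group, at 0.185 ± 0.136 CPM and with 0 CPM in anti-IFN replicate 4, so its fitted fold depends on the prior count. Gm12250, at 0.233 ± 0.0889 CPM, and Ifit3b, at 0.382 ± 0.241 CPM, also lay near that limit in the anti-IFN group. Oas2 came near it in its lowest anti-IFN liver, at 0.257 CPM. The same limit holds for the folds of these genes. Apol9a with Apol9b, Ifit3 with Ifit3b, and Tgtp1 with Tgtp2 are near-identical copies, as are several Gbp genes, and how shared reads were split between them is uncertain.

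**Figure D1:**
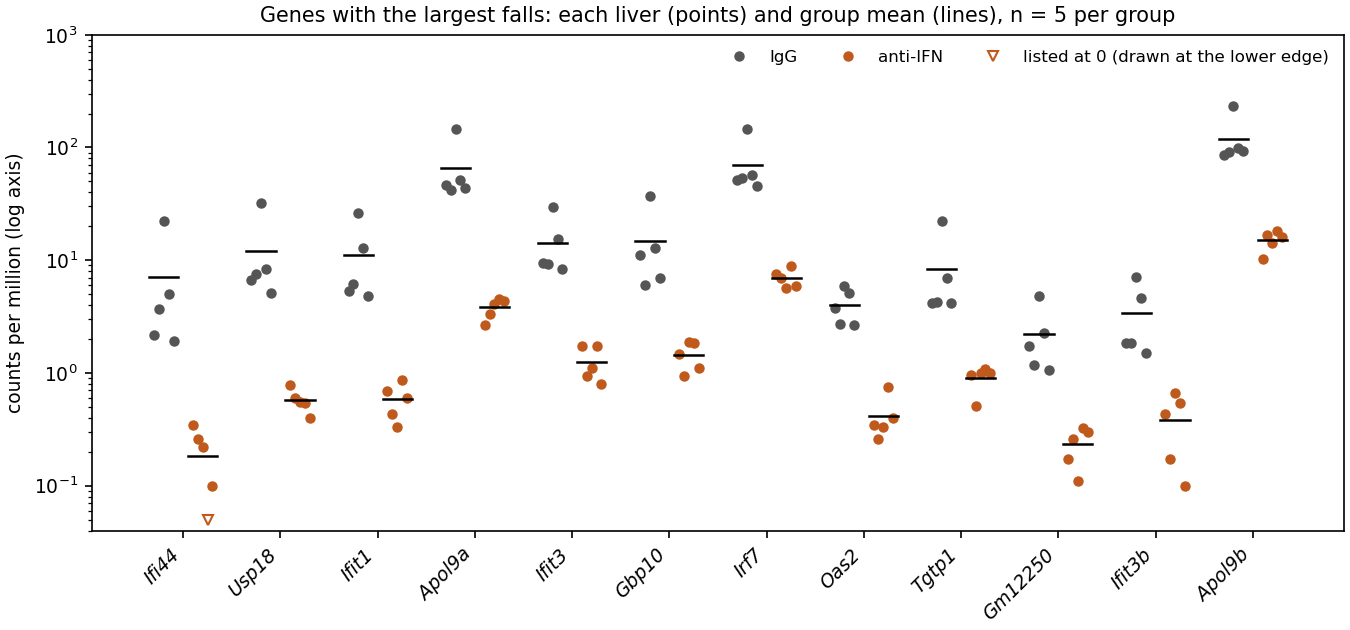
CPM on a log axis for the 12 called genes with the largest falls, for each IgG liver (grey points) and each anti-IFN liver (orange points), with lines at the group means (n = 5 per group). For each gene all 5 anti-IFN livers lie below all 5 IgG livers, with Irf7 at 70.4 ± 42.0 CPM against 6.98 ± 1.31 CPM.

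Type I interferon-stimulated genes fell as a group. All 55 tested members of the fixed list had a negative log2 fold change, with a median of -1.48. Of these, 27 passed the test over all genes and 53 passed when adjusted over the list alone. The camera test gave an adjusted p of 3.47e-185 with the preset correlation, and the list kept its call at an adjusted p = 0.0159 with an estimated correlation. Besides Irf9 and Apol9b, the smallest p among the members belonged to Ifi27, a small membrane protein gene, which fell from 176 ± 84.3 to 30.3 ± 3.35 CPM. Isg15, at 10.9 ± 9.77 CPM with IgG and 2.07 ± 0.557 CPM with anti-IFN, did not pass the test over all genes, with an edgeR adjusted p of 0.0680. It passed without IgG replicate 2 or IgG replicate 3, at an edgeR adjusted p of 0.0422 and 0.000851. The log2 fold changes there were -2.59 and -1.66, against -2.39 with all livers. With all livers it passed in the DESeq2 Wald test (adjusted p of 0.00114) and in edgeR with no filter on low counts (0.0214). In edgeR it also passed with doubled values in place of rounding (0.0377) and with the clock index as a covariate (0.0301).

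Interferon-gamma-inducible genes fell as well, with a median log2 fold change of -0.94 over 30 tested members, of which 29 were negative. Of the 30, 12 passed over all genes and 24 when adjusted over the list alone. The camera adjusted p was 2.86e-63 with the preset correlation, and the adjusted p = 0.0179 with an estimated correlation. The immunity-related GTPase genes Igtp and Irgm2 fell, from 37.8 ± 10.3 to 11.3 ± 1.74 CPM and from 58.3 ± 15.4 to 18.9 ± 4.46 CPM. The guanylate-binding protein gene Gbp6 fell from 17.8 ± 11.2 to 2.68 ± 0.939 CPM. Cxcl9, a chemokine that attracts T cells, fell 5.67-fold, with an edgeR adjusted p of 0.00952. Cd274, which encodes the checkpoint ligand PD-L1, stood at 2.31 ± 0.696 CPM with IgG and 1.21 ± 0.443 CPM with anti-IFN, and its edgeR adjusted p of 0.354 did not pass.

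MHC class I antigen presentation genes, which display peptides to cytotoxic T cells, fell by a smaller amount. The median log2 fold change was -0.34 over 26 tested members, of which 23 were negative. Over all genes 5 members passed, and 16 passed when adjusted over the list alone. The camera adjusted p was 7.48e-26 with the preset correlation, and the adjusted p = 0.0269 with an estimated correlation. The peptide transporter gene Tap1 had a log2 fold change of -1.01 (SE 0.14), H2-D1 of -0.55 (SE 0.08) and H2-Q6 of -0.68 (SE 0.10). MHC class II genes, which display peptides to helper T cells, had a median of -0.65 over 11 tested members, all 11 negative. In edgeR 0 of these passed over all genes, where 6 passed when adjusted over the list alone. The camera adjusted p for class II was 1.57e-09 with the preset correlation, and the call was lost at an adjusted p = 0.224 with an estimated correlation. Cd74, the invariant chain, stood at 125 ± 29.8 CPM with IgG and 69.7 ± 28.5 CPM with anti-IFN, and H2-Ab1 at 35.9 ± 11.1 and 19.8 ± 7.41 CPM. In the DESeq2 Wald test with all livers Cd74, H2-Ab1 and H2-Eb1 passed, at an adjusted p of 0.0255, 0.043 and 0.0217. In edgeR Cd74 and H2-Ab1 passed without anti-IFN replicate 4, at an adjusted p of 0.0101 and 0.0396. That liver had a class II score of 3.68 and the highest scores of the 10 livers for Kupffer cell and macrophage markers (5.08) and for B and plasma cell markers (1.83).

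**Figure D2:**
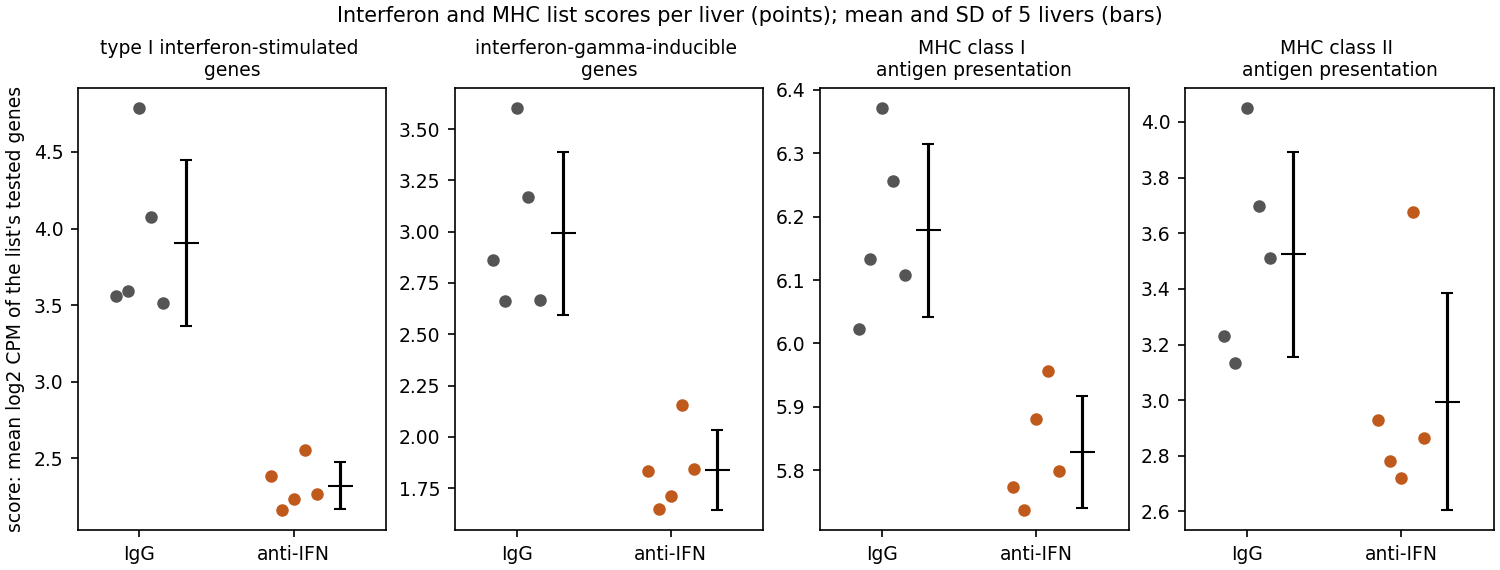
Score of each liver for the 4 interferon and MHC lists, as the mean log2 CPM of the tested genes of a list, with bars at the mean ± SD of 5 livers and a separate vertical axis, which does not start at 0, for each list. The type I score was 3.90 ± 0.54 with IgG and 2.32 ± 0.15 with anti-IFN, and the class II scores of the groups overlap.

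The per-liver scores gave the same view with 1 value per animal. The type I score differed by -1.58, the gamma score by -1.15 and the class I score by -0.35 between the groups on the log2 scale. In these 3 lists all 5 anti-IFN livers lay below all 5 IgG livers. The two-sided exact permutation p was 0.00794 for each, the smallest that regrouping 5 against 5 livers allows, and 0.106 after adjustment over 40 lists. For class II the difference was -0.53, with an exact permutation p of 0.0635.

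Interferon receptor transcripts did not differ past the test. Ifnar1 was at 37.8 ± 2.16 CPM with IgG and 38.9 ± 1.98 CPM with anti-IFN, and Ifnar2 at 67.1 ± 3.69 and 69.2 ± 7.90 CPM. Ifngr1 was at 19.4 ± 3.64 and 19.6 ± 2.72 CPM, and Ifngr2 at 15.5 ± 1.76 and 14.7 ± 1.79 CPM. Over the list of interferon ligands, receptors and kinases, 0 of 12 tested members passed in edgeR, and the median log2 fold change was 0.04. The kinase gene Jak1 had a log2 fold change of 0.10 (SE 0.07) and the feedback inhibitor gene Socs3 of 0.30 (SE 0.27).

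The 4 interferon and MHC lists held 44 of the 52 called genes, from 120 of the tested genes. The odds ratio was 866, with a one-sided Fisher's exact p of 4.58e-84. That p counts genes as independent and does not measure the spread between livers. List members moved together across the livers, with an estimated correlation of 0.726 for type I and 0.459 for gamma-inducible genes. The other 8 calls were Adar, Rnf31, H2-L, H2-Q8, Znfx1, Gm6548, Trim30d and Siglec1, named here because they are few and chosen after their values were seen. Adar, which edits adenosines in double-stranded RNA, fell from 30.9 ± 6.78 to 15.8 ± 0.705 CPM and belongs to the nucleic acid sensing list. In that list 1 of 17 tested members passed, the median was -0.08, and the camera adjusted p was 0.00514 with the preset correlation, lost at an adjusted p = 0.224 with an estimated correlation. Siglec1, a macrophage lectin, had a log2 fold change of -1.50 (SE 0.29). Of these 8, 4 lost the call in some alternatives: Siglec1 in 12 of 21 (each left-out liver but IgG replicate 2 and anti-IFN replicate 4, and 4 others; adjusted p up to 0.157), Trim30d in 8 (without IgG replicate 4 or 5 or anti-IFN replicate 1, 2, 3 or 5, and 2 others; up to 0.133), Gm6548 in 6 (without IgG replicate 1 or 4 or anti-IFN replicate 1, 2, 3 or 5; up to 0.0895) and Znfx1 in 2 (without anti-IFN replicate 1 or 3; up to 0.0607). Their log2 fold changes stayed negative in every alternative. Rnf31, with a log2 fold change of -0.56 (SE 0.08), ends 314 bases upstream of Irf9 on the same strand.

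Some marker lists of other liver cells were called with the preset correlation but not with an estimated one. Camera with the preset correlation called 20 of the 40 lists, and 26 of 100 splits of the livers, the real one included, gave at least as many. Among the lists for RNA quality, cytosolic ribosomal protein genes had a median log2 fold change of 0.10, with 29 of 30 members positive. Their camera adjusted p was 5.53e-06, lost at an adjusted p = 0.442 with an estimated correlation, and their scores gave an exact permutation p of 0.0476, or 0.222 after adjustment. Replication-dependent histone genes were not called, with a median of -0.21 and a camera adjusted p of 0.111. Without anti-IFN replicate 2 or anti-IFN replicate 3 the histone list was called, at a camera adjusted p down to 0.00909. Kupffer cell and macrophage markers had a median log2 fold change of -0.24 over 20 tested members. Of these markers 0 passed in edgeR over all genes, and 3 passed as lower when adjusted over the list alone. Their camera adjusted p was 1.64e-05 with the preset correlation, lost at an adjusted p = 0.443 with an estimated correlation. T and NK cell markers had a median of -0.70 over 7 members, with a camera adjusted p of 0.00887, and an adjusted p = 0.224 with an estimated correlation. The T and NK call also ended without IgG replicate 3, at a camera adjusted p of 0.0773. Dendritic cell markers had a median of -0.12 over 6 members, with a camera adjusted p of 8.69e-05 and an adjusted p = 0.115 with an estimated correlation. The 1 called member there was Bst2, an interferon-inducible membrane protein that also stands in the type I list. Stellate cell and fibroblast markers had a median of -0.23 over 18 members, with a camera adjusted p of 0.00114 and an adjusted p = 0.551 with an estimated correlation. Without IgG replicate 3 that median was -0.07, with a camera adjusted p of 0.476.

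**Figure D3:**
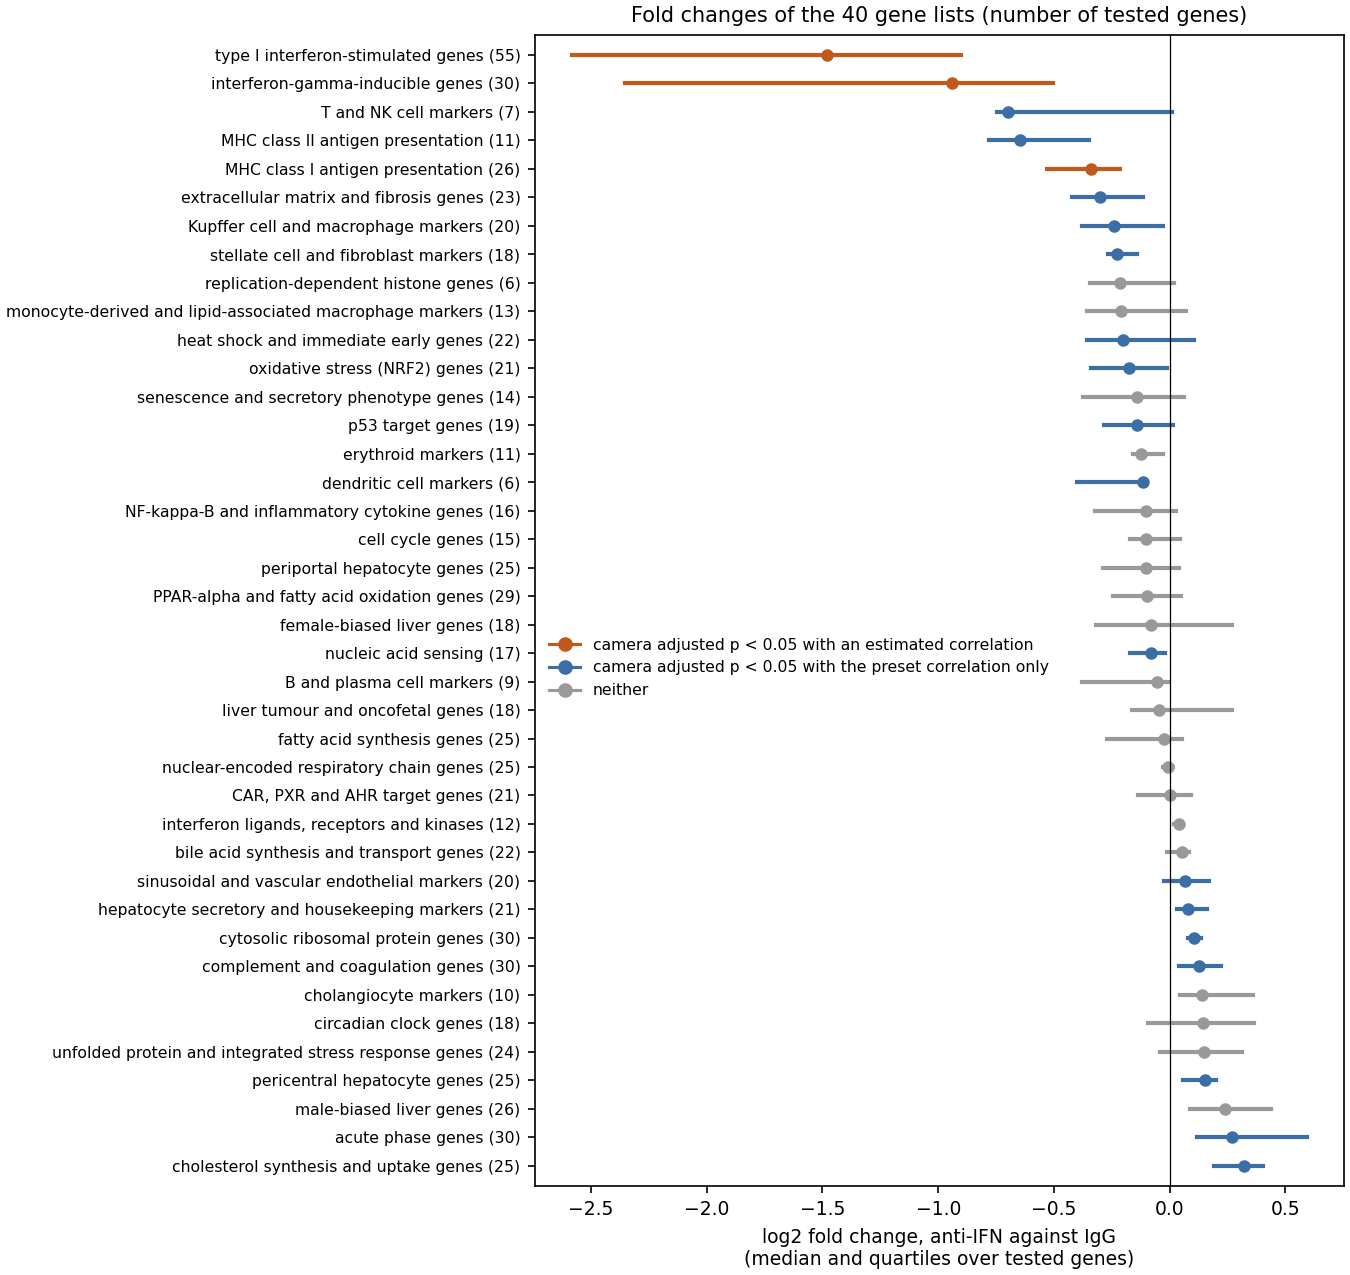
Median (point) and quartiles (line) of the log2 fold changes, anti-IFN against IgG, over the tested genes of each of 40 lists, coloured by whether camera called the list with an estimated correlation, with the preset correlation alone, or with neither. The type I, gamma and class I lists, with medians of -1.48, -0.94 and -0.34, are the 3 called with an estimated correlation.

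No gene passed as higher in edgeR. The 5 genes with the smallest p among those with a positive log2 fold change were Abca8b, Enho, Vps13c, 1810008I18Rik and Ahsg. Abca8b, a lipid transporter gene, was at 61.1 ± 2.40 CPM with IgG and 76.2 ± 5.32 CPM with anti-IFN, with an edgeR adjusted p of 0.0557. Enho, which encodes the secreted peptide adropin, was at 18.8 ± 11.6 and 45.4 ± 6.37 CPM, with an edgeR adjusted p of 0.106. Ahsg, which encodes the plasma protein fetuin-A, was at 5606 ± 726 and 7439 ± 450 CPM, with an edgeR adjusted p of 0.164. Enho passed in edgeR without IgG replicate 4, at an adjusted p of 0.000608, and Ahsg without IgG replicate 3, at 0.0439. In the DESeq2 Wald test with all livers each of the 5 passed. The adjusted p there was 0.00215 for Abca8b, 0.0441 for Enho, 0.0421 for Vps13c, 0.0226 for 1810008I18Rik and 0.0025 for Ahsg. With limma-voom and library weights Abca8b (0.0402) and Enho (0.0475) passed. Enho also passed in edgeR with no filter on low counts (0.0419) and with the clock index as a covariate (0.0406).

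Among the 12 called genes with the largest falls, 5 calls were lost in some fits with 1 liver left out. The log2 fold changes of these 5 genes stayed between -6.07 and -2.42 in every alternative. Ifi44, Tgtp1 and Ifit3b lost the call without IgG replicate 4 and without each anti-IFN liver, Gbp10 without anti-IFN replicate 1, 2 or 5, and Gm12250 without anti-IFN replicate 1, 2, 3 or 5. The highest edgeR adjusted p with 1 liver left out was 0.133 for Ifi44 (without anti-IFN replicate 5) and 0.128 for Ifit3b (without anti-IFN replicate 2). It was 0.111 for Tgtp1 and 0.0615 for Gbp10 (both without anti-IFN replicate 2), and 0.0836 for Gm12250 (without anti-IFN replicate 1). With robust fitting, which left the log2 fold changes as they were, 5 of the 12 lost the call, with an edgeR adjusted p of 0.208 for Ifi44, 0.132 for Tgtp1, 0.109 for Gbp10, 0.0812 for Ifit3b and 0.0538 for Usp18. With limma-voom and library weights it was 0.0601 for Gbp10 and 0.0594 for Tgtp1.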

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

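All tests of explanations in this part, apart from the splits for the number of lists, were chosen only after the result was seen. A liver was singled out where its gap to the nearest other liver of its group divided by the group's range exceeded Dixon's critical value for 5 samples. Of 212 groups of 5 values looked at, 17 passed this limit, where chance gives about 1 in 20 groups, or 10.6. Of the 17, 9 were the same liver, IgG replicate 3.

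IgG replicate 3 stood above the other 4 IgG livers in interferon-stimulated genes and in connective tissue genes. Its gap was 0.738 of the range for Usp18, 0.848 for Apol9a, 0.814 for Irf7, 0.869 for Apol9b, 0.771 for Isg15 and 0.790 for Ifi27. It was 0.820 for the collagen gene Col1a1, 0.733 for the stellate cell and fibroblast score (4.52, against at most 3.86 in the others) and 0.764 for the extracellular matrix score (4.56, against at most 3.75).

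Whether IgG replicate 3 held more non-parenchymal cells of every kind was tested by its stellate score minus its endothelial score, which lay 14.3 SD above the mean of the other 4 IgG livers. The stellate score was also among the values that singled out this liver, and the SD comes from 4 livers, so the 14.3 SD partly restates that flag. The endothelial score of IgG replicate 3 was 4.55, against a mean of 4.52 in the others, so an excess of every kind at once is argued against. Other such scores were higher in this liver, so an excess of some kinds stays open: monocyte-derived macrophage markers were at 3.39 against a mean of 2.51 in the other IgG livers and dendritic cell markers at 3.22 against 2.82 (each 2.96 SD above the other 9 livers), and T and NK, B and plasma, and Kupffer cell markers lay 1.90, 1.51 and 1.27 SD above the other 9. A lesion with dividing cells in the sampled piece remains open: its cell cycle score lay 1.97 SD and its tumour and oncofetal score 2.26 SD above the other 9 livers, the highest of the 10 in both, but under the 3 SD set as the limit. No histology or batch label bears on it, and a difference in the biology of this animal was not tested.

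For the fall of the type I list, candidate explanations are that liver alone, fewer immune cells in the anti-IFN livers, and differences in clock phase between livers. Without IgG replicate 3 the type I score still differed by -1.36, and all 5 anti-IFN livers lay below the 4 IgG livers, with an exact permutation p of 0.00794. Per liver, the type I score fell by more than the score of each of 5 immune cell lists, with a smallest excess of -1.24 (against T and NK cell markers, exact permutation p of 0.00794). T and NK markers were low (Lck at 1.64 CPM with IgG), where the prior count shrinks score differences. Their score, a mean over members, differed by -0.34, against a median log2 fold change of -0.70 with 2 of 7 members positive. The prior count also shrinks differences of low type I members, so that excess is uncertain and may be overstated. With the clock index as a covariate the median of the type I list was -1.53. These values argue against each as the whole cause, and a smaller share of the fall from immune cells stays open.

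The number of called genes was compared with other splits of the 10 livers into 5 and 5. Of 100 splits, 1 (the real one, with 52 genes) gave as many, and the highest other gave 17. Chance is therefore an unlikely source of that count, but it is not excluded. Only 100 of the 126 possible splits were drawn. The other splits mix both treatments, so they do not show what livers without a group difference would give. Nor can chance be excluded for the number of lists that camera called with the preset correlation. There 26 of 100 splits gave at least the real count of 20, and the highest other gave 27.

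Other livers that stood apart are given as values. Anti-IFN replicate 4 was high in the MHC class II score (0.784 of the range), H2-Eb1 (0.714) and Ptpn6 (0.834). IgG replicate 4 was low in the hepatocyte secretory score (0.880), at 11.91 against 11.97 to 11.98. IgG replicate 1 was low in H2-Q6 (0.803) and Klrk1 (0.759), anti-IFN replicate 2 was low in Tgtp1 (0.823), and anti-IFN replicate 3 was high in Angptl6 (0.766).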

How the results depend on the processing

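The alternatives with doubled values, header totals and the clock index were chosen after seeing the data. The main test called 52 genes, 0 of them higher. The DESeq2 Wald test called 113, with 97 lower and 16 higher, and these held all 52. The count of higher genes was 2 with limma-voom, and 1 (Enho) with no filter on low counts. It was 1 (Enho) with the clock index as a covariate, and 1 (Abca8b) at an adjusted p under 0.1. It ran from 0 to 2 with a liver left out, being 2 without IgG replicate 3 (Ahsg and Gm30505) and 2 without IgG replicate 4 (Cyb561 and Enho); Gm30505 and Cyb561 are named after their values were seen. The cause of these differences was not tested. Under the other scalings, filters and fits the total ran from 42 with robust edgeR, which kept 41 of the 52, to 69 with no filter. It ran from 35 to 59 with a liver left out. Of the 52 calls, from 34 (without anti-IFN replicate 1 or 3) to 50 (without IgG replicate 3) were kept there. Camera called 20 lists, but 3 with an estimated correlation and 4 with fry, which do not assume a low fixed correlation between genes, and from 15 to 27 with a liver left out. The MHC class II median of -0.65 was past the threshold with the preset correlation only, with an adjusted p of 0.224 with an estimated correlation and 0.212 with fry. The type I, gamma and class I medians kept their direction and their call in all 16 alternatives each. The ranges were -1.68 to -1.16, -1.05 to -0.66 and -0.39 to -0.26. All of these used the preset correlation except the estimated correlation and fry, which were run with all livers only. Whether the calls hold under those 2 tests with a liver left out was not tested. The scores of these lists kept their direction too. The exact permutation test adjusted over 40 lists, however, cannot pass with these group sizes unless more lists reach the smallest p. Of the 155 genes under the naming rule, 24 passed, and 0 changed direction against their call; in all, 33 alternative values of these genes lost a call and 31 gained one. Depth limits low genes such as Ifi44. No paired analysis was possible because the labels give the animals no replicate numbers that link the groups.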

Other observations

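Acute phase genes, whose transcripts the liver raises during inflammation, had a median log2 fold change of 0.27 over 30 tested members, 27 of them positive. In edgeR 0 passed over all genes and 7 when adjusted over the list alone. The camera adjusted p was 3.28e-09, lost at an adjusted p = 0.224 with an estimated correlation, and 4 of 5 anti-IFN scores lay above all IgG scores. Itih3 was at 1041 ± 194 CPM with IgG and 1630 ± 448 CPM with anti-IFN (SD, n = 5), and Orm2 at 7.00 ± 2.64 and 32.6 ± 37.5 CPM, with 98.0 CPM in anti-IFN replicate 3. The log2 fold change of Orm2 was 2.22, and 1.22 without that liver. Saa2 ranged from 4.82 to 30.1 CPM with IgG and from 4.97 to 1220 CPM with anti-IFN, the top value again being anti-IFN replicate 3, and its log2 fold change was 4.36, and 1.43 without that liver. Complement and coagulation genes had a median of 0.13 over 30 members, 25 positive, with a camera adjusted p of 3.87e-06, and an adjusted p = 0.108 with an estimated correlation. This was the 1 list besides the type I, gamma and class I lists that fry called, at an adjusted p of 0.0213. Plg, which encodes the precursor of plasmin, was at 2536 ± 153 and 2956 ± 73.0 CPM. Cholesterol synthesis and uptake genes were positive in 25 of 25 tested members, with a median of 0.32 and a camera adjusted p of 7.44e-12, lost at an adjusted p = 0.332 with an estimated correlation. Insig1, a brake on sterol synthesis, was at 357 ± 40.4 and 437 ± 55.3 CPM.

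Extracellular matrix and fibrosis genes had a median of -0.30 over 23 members, with a camera adjusted p of 0.00872, and an adjusted p = 0.607 with an estimated correlation. Without IgG replicate 3 that median was -0.06, with a camera adjusted p of 0.958, and without anti-IFN replicate 5 the adjusted p was 0.106. Hepatocyte secretory markers had a median of 0.08 and endothelial markers of 0.07. Their camera adjusted p of 0.0147 and 0.0411 became an adjusted p = 0.443 and an adjusted p = 0.341 with an estimated correlation. The hepatocyte call was lost without IgG replicate 4, anti-IFN replicate 2 or anti-IFN replicate 3, at up to 0.105, and the endothelial call without any 1 of 7 livers, at up to 0.141. Tumour and oncofetal genes, at a median of -0.05 over 18 members, and cell cycle genes, at -0.10 over 15, were not called by camera, with adjusted p of 0.644 and 0.414. The cell cycle list was called without anti-IFN replicate 1 or anti-IFN replicate 4, at a camera adjusted p down to 0.0192. Markers of B and plasma cells had a median of -0.05 and a camera adjusted p of 0.559.

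Circadian clock genes as a list had a median of 0.14 and a camera adjusted p of 0.414. The members with the smallest p were Usp2, which ranged from 1.75 to 4.98 CPM over the IgG livers and from 1.196 to 12.88 CPM over the anti-IFN livers, Nr1d1, from 96.4 to 176 and from 125 to 203 CPM, and Cry1, from 7.31 to 16.7 and from 6.34 to 14.05 CPM. Dbp, a clock output gene chosen for its spread after its values were seen, ranged from 7.23 to 59.9 and from 7.47 to 104 CPM. Every liver had Dbp either at most at 14.4 CPM or at least at 54 CPM, with livers of both groups on each side. The labels give no time of day for collection.

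The hypotheses in this paragraph were tested only after the pattern was seen. The type I response may have fallen by more than the gamma response. Per liver, the type I score minus the gamma score averaged 0.91 with IgG and 0.48 with anti-IFN, a difference of -0.43 (exact permutation p of 0.00794, and -0.36 without IgG replicate 3, with the same p). The lists share 0 tested members, but both kinds of interferon induce many genes of each, so the difference does not say which interferon was blocked. The blockade may also have evened out the response between livers. The mean absolute deviation of the type I score from the group median was 0.36 with IgG and 0.11 with anti-IFN, a difference of -0.25. The exact permutation p was 0.373, and 0.762 without IgG replicate 3, where the difference was -0.04, so these data do not settle it.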
